A study of Mus musculus with 6 samples.

How the data were processed

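RNA was measured in long-term haematopoietic stem cells (LT-HSCs), the rare bone marrow cells that can rebuild blood formation over a lifetime, from mice aged 2 months that were wild type (WT) or carried a knockout of Hmces. Per the labels' protocols, RNA came from 1500 cells sorted after staining with stem cell antibodies, cDNA was made and amplified with the Smart-seq2 method, 500 pg of cDNA went into each library, and paired-end reads of 150 bp were sequenced. The labels give 3 libraries per genotype, all listed as strain C57BL/6, whereas the design text speaks of duplicates. The 6 libraries in the labels were used. The antibody panel and gates, and the nature of the Hmces allele, are not given in the sources used here. The titles of all 6 libraries, WT included, carry a tag of 13 bp whose meaning is not given.

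The values used were FPKM per gene, a fragment count scaled to transcript length and to the library's mapped total, as deposited by the authors in a table with 1 column per library. The submitters' processing notes name TopHat2 2.1.1, Cufflinks 2.2.1 and the mouse genome build mm9. Alignment options and the gene annotation are not given in the sources used here. FPKM values are estimates scaled to library size and transcript length, so a gene listed at 0 can lack reads or can be a failed estimate. Very short RNAs receive large and noisy values in this unit. The scaling to a fixed total makes every level relative to the other transcripts of the same library. Whether strand was used in counting is not given, so overlapping and antisense genes, and families of near-identical copies, are less certain than single-copy genes.

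The table held 23235 genes with 0 repeated symbols, so no values had to be summed. Of these symbols, 20652 matched a current RefSeq symbol (assembly GRCm38.p6) directly, 2341 matched through a listed synonym and 242 were not matched. The reference was used only for names and for which genes neighbour each other, because its assembly differs from the build named in the processing notes, and no coordinates are given. Hmces was found under its earlier symbol 8430410A17Rik. Genes are named by the symbol in the table, with the current symbol beside it where they differ.

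Depth was not stated in the table and was estimated from the steps of low FPKM values. For 1427 genes with a single annotated transcript over 1500 nt and a mean FPKM below 1, the commonest value in WT replicate 1 was taken as that of 1 fragment, with an assumed fragment length of 200 nt. The other libraries were set against it by the commonest ratio of low values. The estimates were 9700000, 13200000 and 14200000 fragments for WT replicates 1 to 3, and 9500000, 11200000 and 9300000 for Hmces knockout replicates 1 to 3. On this scale 3 fragments of Hmces, with a transcript of 1572 nt, correspond to an FPKM between 0.15 and 0.23. These figures depend on the assumed fragment length and cover counting error only. The reads carry no stated molecular identifiers, so fragments are not independent molecules. No test on counts was run.

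Genes with a mean FPKM of at least 1 over the 6 libraries were tested, 11532 in all. Values were taken to log2(FPKM + 1) with no further scaling and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) with genotype as the only term. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested and genes were called at an adjusted p under 0.05. Every log2 fold change is Hmces knockout minus WT on the log2(FPKM + 1) scale, which understates the change of low genes. Ratios are ratios of mean FPKM. Single values per library were compared with an exact two-sided permutation test, for which 3 against 3 libraries can give no p below 0.1. The labels do not say whether the libraries came from separate mice, so all p-values measure only the spread between these samples, which may be technical.

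The gene lists were written down before the data were examined, 37 in all. They covered stem cell identity, quiescence and activation, DNA replication, mitosis, p53 targets, the main DNA repair and damage tolerance pathways, damage signalling, cytidine deaminases, 5-hydroxymethylcytosine enzymes, interferon and NF-kB responses, nuclear and mitochondrially encoded respiratory genes, glycolysis, oxidative stress, apoptosis, senescence, ribosomal proteins, the unfolded protein response, immediate early and heat shock genes, autophagy, TGF-beta and Wnt signalling, chromatin, and markers of blood lineages and niche cells that a sort of bone marrow could hold. Each list with at least 5 tested members was compared with all other genes by limma's camera with an inter-gene correlation preset at 0.01, adjusted over the 36 lists tested. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in one direction, were run beside it. Fry's mixed test asks whether members change in either direction, and its p-values were not adjusted over the lists. Members were also adjusted over the list alone.

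The genes to be named were set by a rule fixed before the data were examined. Hmces came first. Called genes whose 3 knockout values all lay on one side of the 3 WT values followed, up to 12 per direction by size of change, leaving out predicted genes and small RNAs. A direction with fewer than 5 called genes was filled to 8 with the smallest p-values, given as values alone. For each list discussed, the 4 members with the smallest p-values could be named. Any other gene named was chosen after its values were seen, and the text says so.

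The fitting steps were tested on data simulated from the means of the 11532 genes and limma's moderated spreads. In each of 5 runs of the comparison of Hmces knockout against WT, 200 genes were changed. Moderated spreads vary less between genes than observed ones, so the shares recovered may be too high for genes with a large spread. The share recovered was 31.2% for a log2 change of 1, 85.6% for 2, 96.4% for 3 and 97.6% for 4, and 3.5% of all calls were false. A list of 40 genes shifted by 0.5 was found in 5 of 5 runs and an unshifted list in 0. Simulated genes were drawn independently of each other, so these runs do not cover lists whose members move together. In the real data the estimated correlation between members was 0.65 for ribosomal protein genes.

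Alternatives set before the data were examined were pseudocounts of 0.1 and 0.5, no filter on low values, a minimum mean FPKM of 5, rescaling to a common sum, median-ratio scaling, quantile normalization, a variance model without trend or with robust estimation, the replicate number as a block, each library left out in turn, other thresholds and other set tests. Leaving out microRNA and small nucleolar RNA genes was added after the data were seen. Figures were drawn with matplotlib 3.10.9.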

Results

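Gene expression was measured by low-input RNA sequencing in sorted LT-HSCs from WT and Hmces knockout mice, with 3 libraries per genotype. HMCES is a protein that binds abasic sites in single-stranded DNA and shields them during replication. The comparison asks which transcripts differ between Hmces knockout and WT stem cells, in a study concerned with genome integrity and self-renewal. Estimated depth ran from 9300000 to 14200000 fragments per library. An FPKM of at least 1 was reached by 11166 ± 95.1 genes in WT and 11345 ± 162 genes in knockout libraries (SD, n = 3 each; exact permutation p = 0.3). Ribosomal protein genes took 21.0% ± 0.695 of the FPKM sum in WT and 19.0% ± 1.07 in knockout libraries (SD, n = 3 each; exact permutation p = 0.1). The 50 most abundant genes took 23.4% ± 2.19 in WT and 24.5% ± 1.29 in knockout libraries (SD, n = 3 each; exact permutation p = 0.6). Knockout replicate 2 stood apart on the first principal component, with a score of 67.0 against scores between -33.6 and 10.1 for the other libraries.

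Hmces itself, listed as 8430410A17Rik, was read at 39.5, 45.4 and 41.0 FPKM in the WT libraries and at 8.95, 0.222 and 6.95 FPKM in the knockout libraries. The mean was 42.0 ± 3.03 FPKM in WT and 5.37 ± 4.57 FPKM in knockout cells (SD, n = 3 each), 12.8% of the WT level. Every knockout value lay below every WT value, in the direction the labels give. Knockout replicate 2 held an estimated 3 fragments of the transcript, whereas replicates 1 and 3 held 117 and 89, against 527 to 819 in WT libraries. Whether this remaining transcript came from the altered allele or from other cells in the sort was not tested, and the labels do not describe the allele. The log2 fold change was -3.23 (SE 0.71) and was not called (limma adjusted p = 0.289). Without knockout replicate 2 the change was -2.27 with an adjusted p of 0.046. The exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow.

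**Figure D1:**
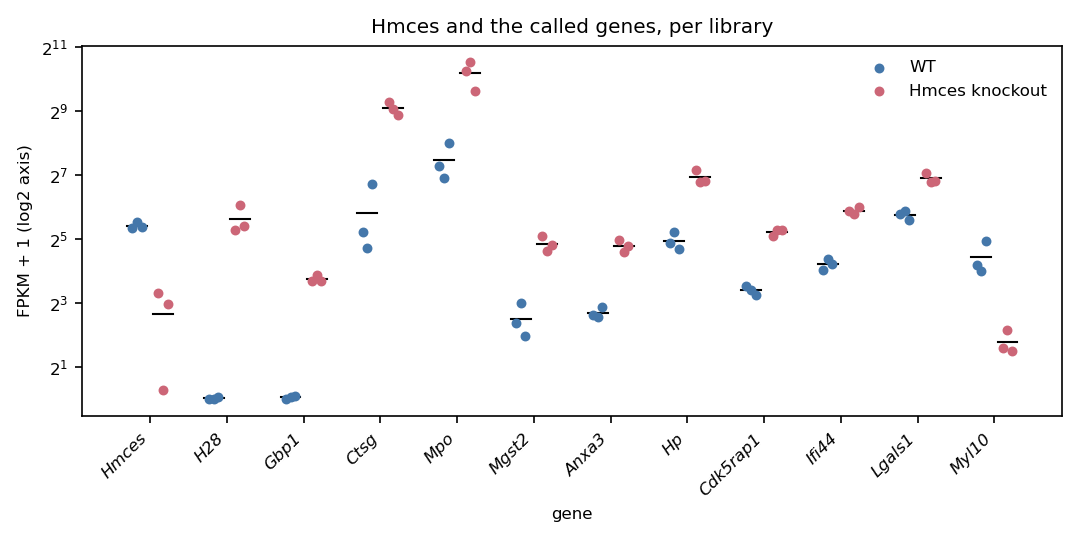
FPKM + 1 on a log2 axis for Hmces and the called genes chosen by the naming rule, with 1 point per library (3 WT in blue, 3 Hmces knockout in red) and a bar at the group's mean FPKM + 1. Hmces lay between 39.5 and 45.4 FPKM in WT and between 0.222 and 8.95 FPKM in knockout libraries.

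Hmces knockout cells had higher levels of a small set of genes. The genes with the smallest p-values were H28 (now Ifi44l), Gbp1 (now Gbp2b), Mir669g and 2310043J07Rik (now Upk3bl), all near or at 0 in WT libraries, and 4 of the called genes were members of the granulocyte and monocyte list. Mpo, which encodes the myeloperoxidase of neutrophil primary granules, rose from 177 ± 71.2 to 1160 ± 348 FPKM, a 6.54-fold difference. Ctsg, which encodes the granule protease cathepsin G, rose from 56.0 ± 43.7 to 544 ± 78.8 FPKM, a 9.71-fold difference that was 17.5-fold without WT replicate 3. Hp, the haptoglobin gene, rose 4.07-fold to 122 ± 18.8 FPKM and the annexin gene Anxa3 rose 4.83-fold to 26.9 ± 3.78 FPKM (SD, n = 3 for each gene). Myl10, a myosin light chain gene, was the 1 gene called lower, at 20.9 ± 8.04 FPKM in WT and 2.49 ± 0.912 FPKM in knockout cells.

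In all, 13 of 11532 genes were called by limma, 12 higher and 1 lower in knockout cells, and 1056 genes had an unadjusted p under 0.05, 498 higher and 558 lower. The groups did not overlap for 1823 genes, 15.8% of those tested, where chance gives 10%. The log2 fold changes were 3.51 (SE 0.45, adjusted p = 0.0494) for Ctsg, 2.73 (SE 0.31, adjusted p = 0.0307) for Mpo, 2.08 (SE 0.21, adjusted p = 0.0146) for Anxa3 and 1.99 (SE 0.18, adjusted p = 0.0102) for Hp. Myl10 fell by 2.62 (SE 0.33, adjusted p = 0.0491). Cdk5rap1, which encodes a tRNA-modifying enzyme, rose 3.77-fold from 9.68 ± 1.09 to 36.5 ± 2.5 FPKM (adjusted p = 0.0119). Mgst2, a glutathione transferase gene, rose 5.90-fold to 28.1 ± 4.71 FPKM (adjusted p = 0.0491), and Lgals1, which encodes galectin-1, rose 2.23-fold to 119 ± 13.4 FPKM (adjusted p = 0.045). Mir669g and 2310043J07Rik (now Upk3bl) were also called and fall outside the naming rule, so they were chosen after their values were seen. Mir669g was listed at 0 in every WT library and at 94.7, 80.6 and 24.2 FPKM in the knockout libraries, and belongs to a family of near-identical microRNA copies. For 2310043J07Rik the table lists 0 in every WT library and 20.4, 11.6 and 26.7 FPKM in the knockout libraries. The number of calls varied with the libraries kept, with 7 genes called without WT replicate 2, 5 without knockout replicate 2 and 2 without knockout replicate 3. Their balance varied too, with 6 higher and 5 lower without WT replicate 1, and 4 higher and 3 lower without WT replicate 2. Small RNA genes were 7 of the 11 calls without WT replicate 1, 4 of 7 without WT replicate 2 and 6 of 19 without WT replicate 3. They were 5 of 11, 1 of 5 and 1 of 2 calls without knockout replicates 1, 2 and 3, against Mir669g alone among the 13. H28 was called under each of the 17 alternative fits, Mpo, Ctsg, Mgst2 and Lgals1 under 8 and Myl10 under 7, while the log2 fold change stayed between 2.48 and 3.03 for Mpo, between 3.09 and 4.10 for Ctsg and between -3.01 and -2.34 for Myl10. The number of calls was 1 with no filter on low values, 6 without the variance trend and 20 with robust estimation. It was 32 without the small RNA genes, a setting added after the data were seen.

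The naming rule, which leaves out predicted genes, added 7 genes with a negative log2 fold change that did not pass the test. Eef2, which encodes a translation elongation factor, had 737 ± 32.3 FPKM in WT and 467 ± 69.6 FPKM in knockout cells (limma adjusted p = 0.187). The cytokine gene Mif had 1283 ± 62.6 and 922.6 ± 43.1 FPKM (adjusted p = 0.194). Otos had 49.9 ± 1.33 and 26.1 ± 3.31 FPKM (adjusted p = 0.133), and Lrrc59 had 57.3 ± 2.45 and 34.1 ± 2.56 FPKM (adjusted p = 0.187). The F-box gene Fbxo9 had 89.5 ± 6.99 and 54.4 ± 5.23 FPKM (adjusted p = 0.190). Rnaset2b, which has a near-identical copy in the genome and is therefore uncertain, had 8.87 ± 0.866 and 2.77 ± 0.594 FPKM (adjusted p = 0.194). Fcna, the ficolin A gene of macrophages, was read at 4.98, 13.1 and 24.4 FPKM in WT libraries and at 0, 1.52 and 0 FPKM in knockout libraries (adjusted p = 0.187).

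Granulocyte and monocyte genes were higher in knockout cells as a group. Of 45 members tested, 39 had a positive log2 fold change, with a median of 0.91. Called over all genes were 4 members, Hp, Anxa3, Mpo and Ctsg, and 27 rose when adjusted over the list alone, with 0 that fell. Camera placed the list above other genes (adjusted p = 2.46e-20), a call not held at adjusted p = 0.122 with an estimated correlation, while fry gave an adjusted p of 0.00822. Elane, the neutrophil elastase gene, and S100a8, which encodes a calcium-binding protein of neutrophils, were chosen after their values were seen. Elane was read at 21.4, 3.07 and 85.5 FPKM in WT libraries and at 1228, 1362 and 915 FPKM in knockout libraries (adjusted p = 0.115 over all genes and 0.000947 over the list alone). S100a8 stood at 4135 ± 1004 FPKM in WT and 9853 ± 2397 FPKM in knockout cells (adjusted p = 0.170 over all genes and 0.00157 over the list alone), so that a transcript of mature neutrophils was abundant in both genotypes. With the small RNA genes left out, 15 members were called over all genes.

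**Figure D2:**
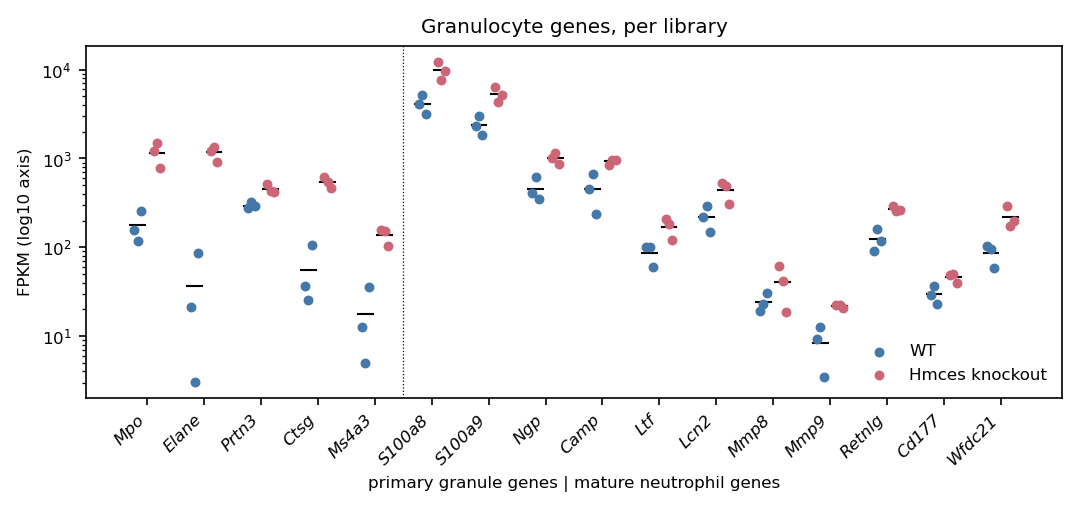
FPKM on a log10 axis for primary granule genes (left of the dotted line) and mature neutrophil genes (right), gene sets chosen after the data were seen, with 1 point per library (3 WT in blue, 3 Hmces knockout in red) and a bar at the group mean. Mpo lay between 119 and 257 FPKM in WT and between 787 and 1476 FPKM in knockout libraries, and S100a8 was at or above 3148 FPKM in all 6 libraries.

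Markers of other lineages that a bone marrow sort could hold gave smaller or more variable differences, and no member of these lists was called over all genes. The mast cell, basophil and eosinophil list had a median log2 fold change of 0.65 over 21 members (camera adjusted p = 0.116), with 0 members adjusted over the list alone. It passed without WT replicate 2 (adjusted p = 0.00413) and without knockout replicate 2 (adjusted p = 0.0193). Hdc, the histidine decarboxylase gene, had 3.29 ± 3.49 FPKM in WT and 13.4 ± 2.27 FPKM in knockout cells, and the mast cell receptor gene Fcer1a had 5.80 ± 5.64 and 16.1 ± 6.08 FPKM. Prg2, which encodes eosinophil major basic protein, was read at 956 FPKM in knockout replicate 1 and at 22.2 and 19.3 FPKM in the other knockout libraries, against 6.32, 5.15 and 11.3 FPKM in WT. Erythroid genes had a median of 0.03 over 29 members (adjusted p = 0.730) and B cell genes 0.23 over 13 members (adjusted p = 0.346). Stromal and endothelial genes had a median of 0.14 over 12 members (adjusted p = 0.365) and lymphoid priming genes -0.03 over 20 members (adjusted p = 0.720). Each of these 4 lists had 0 members adjusted over the list alone. Of 16 T and NK cell genes (median 0.16, adjusted p = 0.365), Il7r and Cd3d rose and Cd2 fell when adjusted over the list alone, all with group means below 6 FPKM. Megakaryocyte and platelet genes had a median of -0.15 over 28 members (adjusted p = 0.720), with 0 adjusted over the list alone, and passed on the lower side without knockout replicate 2 (adjusted p = 0.0171).

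Type I interferon response genes were slightly higher as a group, and a few interferon-related genes differed strongly. H28 (now Ifi44l) was listed at 0, 0 and 0.0642 FPKM in WT libraries and at 37.8, 65.9 and 42.2 FPKM in knockout libraries, a rise of 5.56 on the log2 scale (SE 0.29, limma adjusted p = 0.000702). Gbp1 (now Gbp2b), from a family of similar guanylate-binding proteins, was at 0, 0.058 and 0.0804 FPKM in WT and at 12.1, 13.6 and 11.9 FPKM in knockout libraries, a rise of 3.69 (SE 0.28, adjusted p = 0.0068). Ifi44, an interferon-induced gene next to H28, rose 3.30-fold from 17.8 ± 2.32 to 58.6 ± 4.65 FPKM (SD, n = 3; adjusted p = 0.0119). H28 and Gbp1 were not members of the list. Of 68 list members tested, 49 had a positive log2 fold change, with a median of 0.19. Ifi44 was the 1 member called over all genes and the 1 adjusted over the list alone. D14Ertd668e (now Phf11d) had 1.57 ± 0.287 FPKM in WT and 5.54 ± 1.63 FPKM in knockout cells, Ifi27l1 (now Ifi27) had 224 ± 17.2 and 294 ± 21.8 FPKM, and Oas3 had 17.2 ± 0.882 and 29.8 ± 7.81 FPKM, none of which passed. Camera placed the list above other genes (adjusted p = 0.000579), which did not hold at adjusted p = 0.682 with an estimated correlation, nor with fry (adjusted p = 0.178). In the same knockout libraries the granulocyte marker Mpo was 6.54-fold higher, and a link between it and the interferon list was not tested.

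Ribosomal protein genes and nuclear genes of the respiratory chain were lower as groups by small amounts at the median. Of 80 ribosomal protein genes, 78 had a negative log2 fold change, with a median of -0.19 that was -0.10 under quantile normalization. Rpl21 had 643 ± 55.3 FPKM in WT and 418 ± 64.1 FPKM in knockout cells, and Rps2 had 2926 ± 120.0 and 2418 ± 146 FPKM (SD, n = 3 each). Many genes of this family have processed copies in the genome, so their levels are uncertain. Of 77 respiratory chain genes, 69 had a negative log2 fold change, with a median of -0.18. The ATP synthase gene Atp5g3 had 288 ± 8.85 and 218 ± 15.2 FPKM, and Cox6a1, of cytochrome oxidase, had 775 ± 61.8 and 588 ± 54.0 FPKM. No member of either list was called over all genes or adjusted over the list alone. Camera placed both lists below other genes (adjusted p = 1.99e-07 and 5.70e-05). For both lists this became adjusted p = 0.782 with an estimated correlation, and fry gave an adjusted p of 0.373 for each. Without knockout replicate 2, which stood apart from the other libraries, the respiratory list had a camera adjusted p of 0.0644. In the same knockout libraries Mpo was 6.54-fold higher, and a link between it and these lists was not tested. The mitochondrially encoded list had 0 members matched and got no test.

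Genes of activated multipotent progenitors, which drive growth and cycling, were also lower as a group. Of 34 members, 28 had a negative log2 fold change, with a median of -0.21. Over all genes 0 were called, and adjusted over the list alone 3 fell and 1 rose. Fbl, which encodes the nucleolar methyltransferase fibrillarin, fell from 218 ± 15.5 to 147 ± 16.2 FPKM, the cyclin gene Ccnd1 fell from 5.31 ± 0.197 to 1.60 ± 0.427 FPKM, and the spermidine synthase gene Srm fell from 145 ± 18.0 to 88.7 ± 17.9 FPKM (SD, n = 3; limma adjusted p = 0.0329 over the list alone for each). Cd48, a surface marker of progenitors and mature blood cells, rose from 180 ± 37.7 to 279 ± 24.1 FPKM with the same adjusted p. The camera adjusted p was 0.00143, against adjusted p = 0.682 with an estimated correlation and 0.176 with fry. The knockout libraries also held 6.54-fold more Mpo, and a link between it and this list was not tested.

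**Figure D3:**
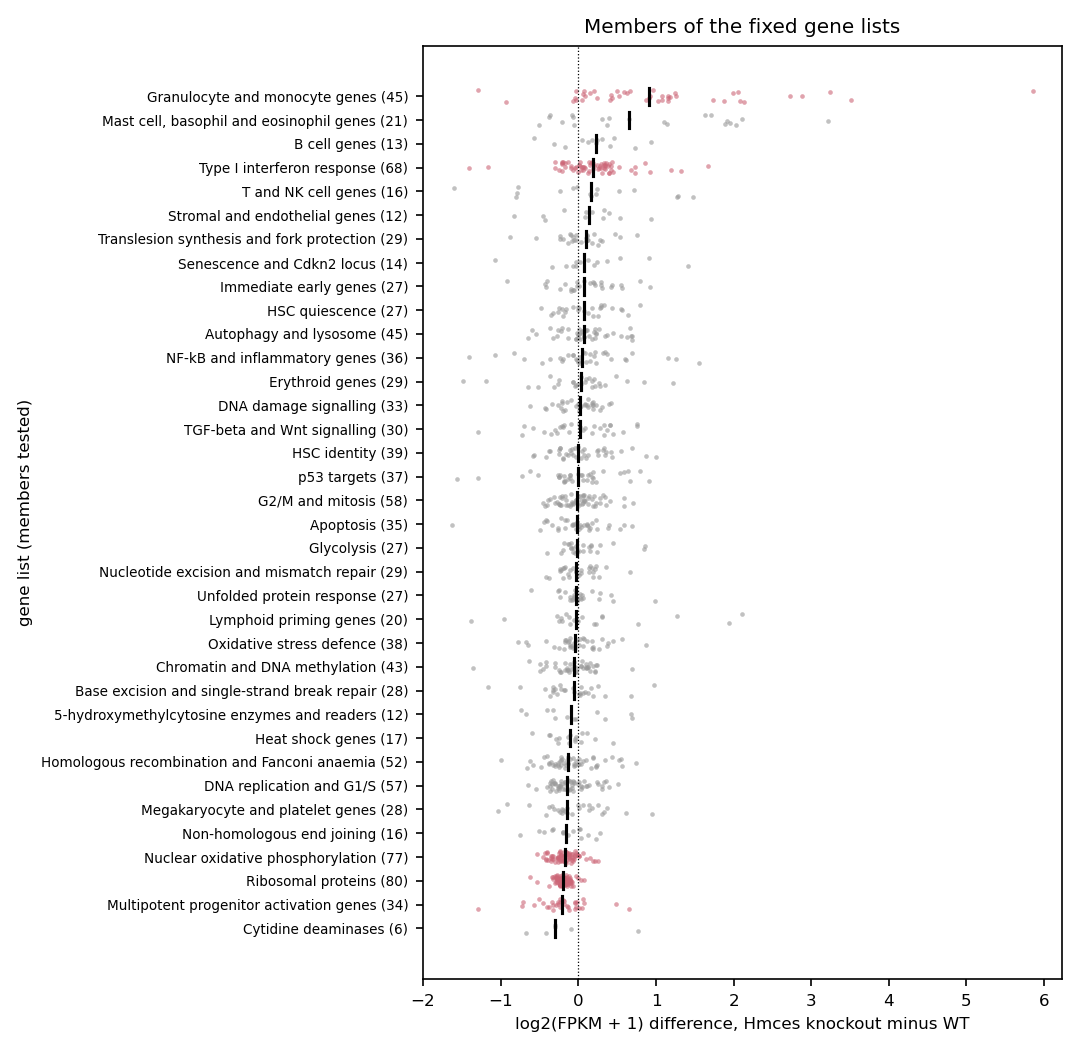
Log2 fold changes (log2(FPKM + 1), Hmces knockout minus WT) of the tested members of 36 gene lists, with 1 point per gene, a bar at the list median and the number of members in brackets. The 5 lists called by camera are in red, and their medians run from 0.91 for granulocyte and monocyte genes to -0.21 for multipotent progenitor activation genes.

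Genes of stem cell identity did not move in one direction as a group. Over 39 members the median was 0.00 and 20 had a positive log2 fold change (camera adjusted p = 0.393). Fry's mixed test, of change in either direction, gave this list an unadjusted p of 0.000425. Over all genes 0 were called, and Esam, an adhesion molecule gene of stem cells and endothelium, was the 1 that rose when adjusted over the list alone, from 66.0 ± 4.87 to 134 ± 18.0 FPKM. Sult1a1 had 8.19 ± 0.649 and 15.9 ± 2.05 FPKM, Pdzk1ip1 had 74.5 ± 7.42 and 100.8 ± 8.24 FPKM, and Ly6a, which encodes Sca-1, had 231 ± 21.7 and 311 ± 48.8 FPKM. Quiescence genes had a median of 0.07 over 27 members (adjusted p = 0.346), with 0 called over all genes and 0 adjusted over the list alone. DNA replication and G1/S genes had a median of -0.14 over 57 members, 41 of them negative, and lay just outside the threshold (adjusted p = 0.0622). Pold2, a subunit of the replicative polymerase, had 89.1 ± 9.92 and 60.5 ± 3.80 FPKM, Uhrf1 had 89.4 ± 10.8 and 67.0 ± 5.92 FPKM, and Mcm5, of the replicative helicase, had 170 ± 6.67 and 137 ± 9.91 FPKM. This list passed without WT replicate 1 (adjusted p = 0.0404), WT replicate 2 (0.0306) or knockout replicate 2 (0.0363), and with no filter on low values (0.00242). G2/M and mitosis genes had a median of -0.01 over 58 members (adjusted p = 0.964). The replication and the mitosis lists each had 0 members called over all genes and 0 adjusted over the list alone.

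The lists closest to the known role of HMCES in DNA damage did not pass the camera test in either direction, and none of their members was called over all genes. Base excision and single-strand break repair genes had a median of -0.06 over 28 members (camera adjusted p = 0.584). The uracil glycosylase gene Ung had 66.1 ± 18.2 FPKM in WT and 38.3 ± 5.71 FPKM in knockout cells, and the glycosylase genes Neil1 and Ogg1 had 8.27 ± 0.576 and 14.2 ± 4.2 FPKM, and 5.17 ± 3.52 and 9.81 ± 0.264 FPKM. Homologous recombination and Fanconi anaemia genes had a median of -0.14 over 52 members (adjusted p = 0.346), and non-homologous end joining genes -0.16 over 16 members (adjusted p = 0.346). Translesion synthesis and fork protection genes had a median of 0.10 over 29 members (adjusted p = 0.687), with the fork-repriming gene Ccdc111 (now Primpol) at 8.35 ± 1.03 and 14.8 ± 1.93 FPKM. Nucleotide excision and mismatch repair genes had a median of -0.03 over 29 members, DNA damage signalling genes 0.02 over 33 members and p53 targets -0.00 over 37 members (adjusted p = 0.874 for each). Each of these 7 lists had 0 members adjusted over the list alone. Of 6 cytidine deaminase and dUTP handling genes (median -0.30, adjusted p = 0.342), the nucleotide hydrolase gene Dctpp1 fell from 269 ± 40.5 to 168 ± 24.1 FPKM and the cytidine deaminase gene Apobec1 rose from 14 ± 0.979 to 25 ± 7.24 FPKM when adjusted over the list alone. Among 12 genes of 5-hydroxymethylcytosine enzymes and readers (median -0.10, adjusted p = 0.730) Dctpp1 was the 1 adjusted over the list alone. Fry's mixed test gave an unadjusted p of 0.000107 for these 12 genes, 0.00466 for the cytidine deaminase list and 0.00584 for p53 targets. For the remaining repair and signalling lists it gave 0.0506 or more. The median, mean and camera direction differed in sign for the mitosis, p53, nucleotide excision, damage signalling, erythroid and lymphoid priming lists.

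Genes within 1 Mb of Hmces were examined as possible bystanders of the edit. Of 34 such genes in the table, by their order in assembly GRCm38.p6, 24 were tested and 0 were called by limma, with 3 at an unadjusted p under 0.05 and 0 adjusted over the neighbours alone. These 3 were Isy1 (90.2 ± 7.82 FPKM in WT and 65.7 ± 3.23 FPKM in knockout cells), Ccdc48, now Efcc1 (13.7 ± 3.37 and 7.72 ± 1.36 FPKM), and Rab7 (192 ± 14 and 158 ± 6.74 FPKM), chosen after their values were seen. In total 14 of the 24 had a negative and 10 a positive log2 fold change.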

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

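Leaving out the small RNA genes was the alternative chosen after the data were seen, and all others were set beforehand. The count of 13 called genes (12 higher, 1 lower) became 1 (1 and 0) with no filter on low values, 6 (6 and 0) without the variance trend, 20 (19 higher) with robust estimation and 32 (30 and 2) without small RNA genes, where the prior degrees of freedom went from 3.89 to 6.99. Rescaling to a common sum called 0 genes lower. Leaving out 1 library at a time gave 2 to 19 genes, 2 to 16 of them higher and 0 to 5 lower. These calls included small RNA genes, as many as 7 of 11 without WT replicate 1. Of the 13 genes, 4, 3 and 10 were still called without WT replicates 1, 2 and 3, and 6, 3 and 2 without knockout replicates 1, 2 and 3. Other pseudocounts, filters, scalings and thresholds kept the total within 1.5 times. With the replicate number as a block 2 genes were called, both higher and 0 lower. Deviations of same-numbered libraries correlated at 0.0803, 0.0105 and 0.0352, and the libraries of number 3 did not correlate best with each other, so the numbers are not taken as pairs. With 1 library left out the Hmces change ran from -3.78 to -2.27, past the threshold only without knockout replicate 2.

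For the lists called by camera, the adjusted p with an estimated correlation was 0.122 for granulocyte, 0.682 for interferon, 0.682 for progenitor activation and 0.782 for ribosomal and for respiratory genes. Fry gave 0.178 for interferon, 0.176 for progenitor activation and 0.373 for ribosomal and for respiratory genes. Leaving out 1 library gave the respiratory list adjusted p values from 3.46e-07 to 0.0644, while the other 4 called lists kept their call, with ribosomal genes between 7.87e-10 and 0.0171, interferon genes between 8.14e-05 and 0.0267, progenitor activation genes between 0.000891 and 0.0344 and granulocyte genes between 6.17e-20 and 2.24e-12. DNA replication genes passed with no filter (0.00242) and ranged from 0.0306 to 0.432 with 1 library left out. The same ranges were 0.0171 to 0.912 for megakaryocyte genes and 0.00413 to 0.596 for mast cell genes. The 5 called lists kept their direction in all 19 alternatives, and their medians kept their sign under the 3 other scalings, with ribosomal genes between -0.19 and -0.10. Of 582 values of uncalled lists 32 had the other sign. Of 2458 values of single genes 77 lost and 10 gained a call and 0 of the called ones reversed. The cause of these changes was not tested. Fits that left 1 library out differed both in the number of libraries and in which were kept. Keeping repeated symbols apart was not run because there were 0. Depth limits Hmces in knockout replicate 2, at 0.222 FPKM with 3 fragments equal to 0.19 FPKM.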

Other observations

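The tests of the granulocyte pattern, of the genes near 0 in one genotype and of the ribosomal and respiratory levels and shares per library were chosen only after the results were seen, while those of transcript length and other splits were set beforehand.

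A few inflammatory and granulocyte genes passed within lists that did not pass as groups, and no member of these lists was called over all genes. Of 36 NF-kB and inflammatory genes (median log2 fold change 0.05, camera adjusted p = 0.346), 3 rose when adjusted over the list alone. They were Ptgs2, the prostaglandin synthase gene, from 2.06 ± 0.606 to 8.11 ± 2.86 FPKM, and S100a8 and S100a9, which the granulocyte list also holds. Of 38 oxidative stress genes (median -0.04, adjusted p = 0.874), the glutathione transferase gene Gstm1 rose from 99.2 ± 8.24 to 183 ± 22.3 FPKM when adjusted over the list alone, and it too belongs to the granulocyte list. Heat shock genes had a median of -0.10 over 17 members (adjusted p = 0.342), with Hspe1 at 296 ± 8.94 FPKM in WT and 228 ± 21.0 FPKM in knockout cells. Immediate early genes had a median of 0.07 over 27 members (adjusted p = 0.346), with Btg2, an antiproliferative gene, at 46.5 ± 3.63 and 83.3 ± 22.5 FPKM. Autophagy and lysosome genes had a median of 0.07 over 45 members, 31 of them positive (adjusted p = 0.346).

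The medians of other cell state lists lay near 0. Glycolysis genes had a median of -0.02 over 27 members (camera adjusted p = 0.751), with the glucose transporter gene Slc2a1 at 10.01 ± 1.90 and 18.9 ± 4.07 FPKM. Unfolded protein response genes had a median of -0.03 over 27 members (adjusted p = 0.874), with the asparagine synthetase gene Asns at 25.8 ± 9.35 and 50.2 ± 5.26 FPKM. Apoptosis genes had a median of -0.02 over 35 members (adjusted p = 0.874) and senescence genes 0.07 over 14 members (adjusted p = 0.440). TGF-beta and Wnt signalling genes had a median of 0.02 over 30 members (adjusted p = 0.874) and chromatin and DNA methylation genes -0.05 over 43 members (adjusted p = 0.598). Fry's mixed test gave an unadjusted p of 1.17e-05 for the TGF-beta and Wnt list and 0.0838 or more for these other cell state lists. Apart from the NF-kB and oxidative stress lists, these lists had 0 members adjusted over the list alone. The median, mean and camera direction differed in sign for the glycolysis, unfolded protein response and TGF-beta lists.

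Higher granulocyte and monocyte genes in knockout LT-HSCs may reflect other cells in the sort or transcription in the stem cells themselves. A lower share of stem cells, with marrow cells of every kind in their place, would raise the markers of each other cell type alike. However, 4 of the 6 other cell type lists (B cell, erythroid, megakaryocyte, stromal) had bootstrap intervals of the median wholly below the granulocyte interval of 0.50 to 1.15. The intervals came from resampling genes within a list, so they hold no spread between libraries. Stem cells replaced by granulocytes or their progenitors alone would leave the other lists flat, so these intervals do not speak to that case. RNA from mature neutrophils alone was taken to raise primary granule genes no more than mature neutrophil genes. The mean log2 fold change was 3.19 for 5 primary granule genes (from 0.62 for Prtn3 to 5.86 for Elane) and 1.08 for 11 mature neutrophil genes. The gap was 2.11, with every knockout library above every WT library (exact permutation p = 0.1). The gap stayed under 2 times the WT SD of 1.39, so the source is not excluded. A log2 change also depends on the starting level, in WT 3.07 to 85.5 FPKM for Elane and 4135 FPKM for S100a8. Added RNA raises a low gene more on this scale whatever its source, so the direction of the gap does not decide. WT replicate 3 had the highest WT values of Elane, Ctsg and Ms4a3, and without it the Elane ratio went from 31.9 to 95.5. Carry-over of granulocyte-monocyte progenitors stays open, because 85% of 20 progenitor markers (17) had a positive change but all 20 belong to the granulocyte list that prompted the test, and the myeloid regulators and growth factor receptors among them went both ways, with Cebpa at -0.94 (SE 0.65), Csf3r at -0.04, Csf1r at 0.06 (SE 0.51), Irf8 at 0.08 (SE 0.24) and Cebpe at 1.15 (SE 0.29). The stem cell sort should remove mature cells, yet S100a8 stood at 4135 FPKM in WT, and a response of the stem cells to the loss of Hmces stays open and untested.

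Genes near 0 in WT and clearly read in knockout cells, such as H28, Gbp1 and 2310043J07Rik, might mark genome stretches of another strain in the knockout mice, although the labels give C57BL/6 for all libraries. These genes were not among the 24 tested genes within 1 Mb of Hmces, of which 0 were called. H28 is known as a minor histocompatibility gene, a class that differs between inbred strains. Among 35 genes with an unadjusted p under 0.001, granulocyte genes left out, 5 lay within 1 Mb of another, in 2 stretches (Ifi44 with H28, and 2310043J07Rik with Myl10 and 4933404O12Rik), against a mean of 2.05 in random sets (one-sided permutation p = 0.0865), which does not decide. The other 67 interferon list members still lay above other genes (camera adjusted p = 0.00155 without Ifi44). For the full list the call was lost with an estimated correlation (camera adjusted p = 0.682) and with fry (adjusted p = 0.178). The median log2 fold change of the 67 was 0.18 (95% bootstrap interval 0.07 to 0.29, from resampling genes and not libraries). In these libraries the list as a whole thus did not rise by this size. An interferon response limited to a few genes is not excluded. Sequence variants in the reads, which were not analysed here, would settle the origin of these stretches.

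Lower ribosomal protein and respiratory chain genes may rest on single libraries or on genotype, and the measures per library point both ways. The median levels of both lists overlapped between genotypes, with knockout replicate 2 lowest for both (10.4 and 7.97 log2 units against WT means of 10.8 and 8.29). The share of the FPKM sum did separate them, at 19.7%, 17.8% and 19.5% in knockout against 20.7%, 21.8% and 20.5% in WT libraries for ribosomal genes, and 3.53% ± 0.193 against 3.96% ± 0.087 for respiratory genes (SD, n = 3; exact permutation p = 0.1 for each), so that for each list 1 of the 2 measures separated the genotypes and an effect of single libraries cannot be told apart from one of genotype. Without knockout replicate 2 the ribosomal list kept its camera call (adjusted p = 0.0171) and the respiratory list lost it (0.0644). Over all 6 libraries neither list was called by camera with an estimated correlation (adjusted p = 0.782 for each). Transcript length may account for part, since random lists matched on length and expression had medians of -0.10 and -0.11. The observed -0.19 and -0.18 lay at or below percentile 0.14 of 10000 such lists. How close the matches were was not checked. The random lists also draw genes independently, whereas the estimated correlation between members was 0.65 for ribosomal and 0.33 for respiratory genes. The percentile therefore does not decide how much length explains.

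With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split called 13 genes and the highest other split 5, so 1 of the 10 splits reached the real count. For the lists the real split called 5 and the highest other split 9, and 3 of the 10 splits gave at least as many as the real one.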
